A study of Mus musculus with 12 samples.

How the data were processed

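The samples were 12 Affymetrix Mouse 430 2.0 arrays of RNA from sorted cells of mouse embryos at stage E12.5, with 3 biological replicates for each of R+, R-, C+ and C- and 200000 sorted cells per array. The submitters' design text names R+ and C+ as YFP-positive serotonin neurons and R- and C- as YFP-negative cells. Per the labels' protocols, tissue was dissociated with mild trypsin and trituration, cells were sorted into Trizol, and biotinylated cRNA was made with one round of amplification. The submitters' processing notes name MAS5; its version, settings and filters are not given in the sources used here. The deposited values are MAS5 signal intensity on a linear scale, rounded to whole numbers. On every array their mean without the lowest and highest 2% was 500, so that the arrays had been scaled to a common level. No detection calls were used here. The labels call the replicates biological but do not say whether they came from separate litters, so p-values measure the spread between these samples.

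Of 45101 probe sets 64 controls were left out of the tests. Through the probe table, 34945 had one gene symbol, 932 had several and 9160 had none; symbols were checked through Entrez numbers against the RefSeq table of GRCm38.p6, which matched 34741 and changed 0. Probe sets with a signal over 107, the median of all values, on at least 3 arrays were kept (26061, of which 22030 had one symbol). Each gene was represented by its probe set with the highest mean log2 signal, one ending in _x_at only where there was no other (113 genes), which left 12845 genes; 5561 of them had 2 or more kept probe sets. The remaining 4031 kept probe sets without a single symbol were not used for gene results. For the 79 called named results with other kept probe sets, 71 of 108 other probe sets were called in the same direction when all probe sets were fitted, 3 had the opposite sign (of St18 in C+ against C- and in R+ against C+, and of Hoxc5 in the difference of differences), and 0 passed with the opposite sign. No coordinates are given because the array names no genome build.

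Differences were fitted with limma 3.58.1 in R 4.3.3 on log2(signal + 10), where 10 is the 10th percentile of all values. Fold changes of dim genes are understated on this scale. One mean per group was fitted over all 12 arrays, with eBayes moderation with a trend, 5 contrasts and two-sided tests, adjusted by the Benjamini-Hochberg method at 0.05 over all genes for each contrast. The contrasts were R+ against R-, C+ against C-, R+ against C+, R- against C-, and the difference between the last pair. The procedure was tested on simulated data for R+ against R- over 12845 genes: in 5 runs with 200 changed genes each, 9.25% of changes of 0.5, 51% of changes of 1 and 82.4% of changes of 2 on the log2 scale were recovered, and 23 of 63225 unchanged genes were called. The simulated noise was independent between genes and arrays. These rates therefore leave out the correlation by replicate number described below and may not hold for the real arrays. The 200 changed genes were also fewer than the 1567 called between R+ and R-. The adjusted threshold is stricter when fewer genes change, so the recovered shares may be too low.

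There were 23 gene lists with 597 genes, of which 491 were measured; 12 genes stood in several lists. Each list was tested in each contrast with camera at a preset inter-gene correlation of 0.01, adjusted over 115 tests, and members were counted after adjustment over all genes and over the list alone. With this preset 47 tests passed, and 21 of those 47 also passed with an estimated correlation. As many as 47 passed in 14 of 100 regroupings of the arrays, so that member counts and the p with an estimated correlation stand beside the lists that passed. The lists, the contrasts, the filter, the rules for named genes and most alternatives were fixed before the data were examined. Named genes were any list member, and for each comparison the 10 per direction with the largest difference among genes past the threshold, with all 3 arrays of one group above those of the other and a higher group mean over 450. To these were added the 10 genes higher in both YFP-positive populations by the smaller difference, the 10 per direction between R+ and C+ that were also enriched over YFP-negative cells, and the 5 per direction with the smallest adjusted p in the difference of differences. Which list members are quoted was chosen after their values and the stability of their calls were seen.

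The replicate numbers were checked for pairing. In deviations from the group means, arrays with the same number correlated at 0.118 to 0.52 over 18 pairs, and the other 36 pairs of arrays from different groups at -0.398 to 0.273. All 18 were over 0.1. Pairs within replicate 1 lay at 0.334 to 0.52 and those within replicates 2 and 3 at 0.118 to 0.241. Replicate 2 arrays correlated with replicate 3 arrays of other groups at up to 0.273. Replicate 1 thus stood apart, but a pairing within numbers 2 and 3 was not shown. The labels do not say what a number shares. The fit without the block was fixed beforehand and stays the reported one, and blocked counts of genes and of called list members are printed beside it where they differ by over 1.5 times. The 4 replicate 1 arrays had a BioC hybridization control signal of 1936 to 2395, and the others 698 to 1051.

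Alternatives were other offsets, quantile and median scaling, other filters, the mean of a gene's probe sets, no trend, the replicate block, only the arrays compared, each probe set by itself, a minimum of 2-fold, and each array left out in turn. Chosen after the data were seen were replicates 2 and 3 alone, the log2 beta-actin 3'/5' ratio as a covariate, and that ratio with the block. RNA quality ratios were compared between domains with an exact permutation test on their log2 values, within replicate numbers and over all arrays. Shares of genes whose 3 arrays of one group lay wholly above or below those of the other were 28.4% for R+ against R-, 27.3% for C+ against C-, 26.0% for R+ against C+ and 19.2% for R- against C-, where chance gives 10%.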

Results

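Expression was measured in cells sorted from the neural tube of mouse embryos at the embryonic stage E12.5. The embryos carried ePet-EYFP, a transgene in which an enhancer of the Pet-1 gene drives yellow fluorescent protein (YFP) in serotonin neurons. The tissue was divided at the pontine flexure into a rostral domain, reaching up to the mesencephalic flexure, and a caudal domain, reaching down to the spinal cord, and each domain was sorted by flow cytometry into YFP-positive and YFP-negative cells. This gave 4 populations: rostral YFP-positive cells (R+), rostral YFP-negative cells (R-), caudal YFP-positive cells (C+) and caudal YFP-negative cells (C-). Each was represented by 3 biological replicates of 200000 cells, so that n = 3 arrays per group throughout. RNA was hybridized to 12 Affymetrix Mouse 430 2.0 arrays, on which the median signal lay between 93 and 121. Below, signals are means ± SD and differences are on the log2(signal + 10) scale ± SE, the group named first minus the other; the number of arrays limits the precision of both.

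The arrays of the rostral and caudal domains differed in a measure of RNA quality. The ratio of the 3' to the 5' control probe set of beta-actin, which rises as RNA is degraded or incompletely copied, was 3.38 ± 0.61 (SD, n = 6) on the rostral arrays and 5.77 ± 1.31 (SD, n = 6) on the caudal arrays (two-sided exact permutation test over the 216 splits within replicate numbers, p = 0.00926, the smallest it can give). The ratio for Gapdh was 1.43 ± 0.40 and 2.62 ± 1.19 (exact permutation p = 0.0185). Over all 924 splits, which ignore the numbers, p was 0.00216 and 0.0281 by the same exact test. If the YFP-positive and YFP-negative arrays of one dissected domain count as one unit, 8 splits remain and no exact p can be below 0.25, which both ratios had. Within a domain the YFP-positive and YFP-negative arrays lay close together for beta-actin, at 3.24 ± 0.52 in R+, 3.52 ± 0.78 in R-, 5.79 ± 1.20 in C+ and 5.75 ± 1.69 in C- (SD, n = 3 each). The Gapdh ratio was 1.38 ± 0.28 in R+, 1.49 ± 0.57 in R-, 3.20 ± 1.52 in C+ and 2.03 ± 0.48 in C- (SD, n = 3 each). The signal of the 5' control probe set of 18S ribosomal RNA also parted the domains. It was 360 to 1617 on the rostral and 79 to 201 on the caudal arrays. This signal was picked out after the values were seen and was not tested. Only the beta-actin ratio served as a covariate below.

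**Figure D1:**
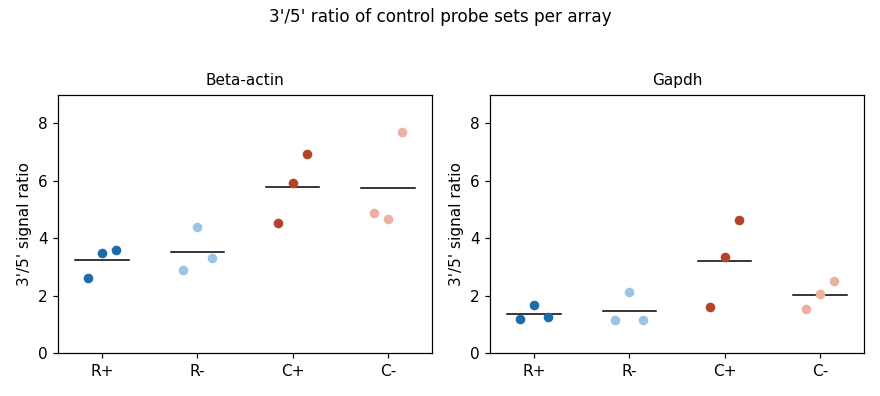
Ratio of the 3' to the 5' control probe set for beta-actin and Gapdh (vertical axis, no unit), with a point per array and a bar at each group mean. All 6 rostral arrays lay below all 6 caudal arrays for beta-actin, with group means of 3.24 and 3.52 against 5.79 and 5.75.

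The comparison of R+ with R- asked which genes mark serotonergic cells of the rostral domain. Genes of serotonin synthesis, storage, uptake and breakdown were higher in R+. Tph2, the rate-limiting enzyme of neuronal serotonin synthesis, had a signal of 6211 ± 605 in R+ and 46 ± 32.9 in R- (log2 difference 6.95 ± 0.34, adjusted p = 4.73e-09). Slc6a4, the serotonin transporter, differed by 6.996 ± 0.32, Slc18a2, the vesicular monoamine transporter, by 5.42 ± 0.18, and Gchfr, the feedback regulator of the cofactor enzyme GTP cyclohydrolase 1, by 7.73 ± 0.34. Gch1, which encodes that enzyme, differed by 4.77 ± 0.45. Of 16 measured members of this list, 11 were higher in R+ and 0 lower (11 and 0 adjusted over the list alone; camera adjusted p = 1.32e-18, and 0.00102 with an estimated correlation). Htr1a, the autoreceptor, differed by 2.22 ± 0.24, while a second Htr1a probe set gave 0.96 ± 0.77 (adjusted p = 0.624). Because the signals of these genes in R- were low, the folds depend on the offset of 10.

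Among 7 measured serotonergic transcription factors 4 were higher in R+ and 1 was lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.00224, and 0.0825 with an estimated correlation). Lmx1b, required for serotonergic differentiation, differed by 3.27 ± 0.28, Gata2 by 2.22 ± 0.15 and Gata3 by 2.81 ± 0.22. The lower one was St18 (-1.82 ± 0.23), whose second probe set gave -0.89 ± 0.75 (adjusted p = 0.648). Pet-1 itself (Fev) was not analysed here. Other genes far higher in R+ were Cryba2 (6.45 ± 0.19), the secretory granule gene Scg2 (4.85 ± 0.13), the homeobox gene Hmx2 (5.80 ± 0.38) and the transcriptional coregulator Cited1 (4.83 ± 0.67). 1700042O10Rik (5.18 ± 0.39) is annotated within the span of Ddc in the RefSeq annotation of GRCm38.p6, so its signal is uncertain. Chgb, a granin of dense-core vesicles, reached 32519 ± 5634 in R+ and 3486 ± 587 in R-.

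Many genes of glutamate, GABA and glycine neurons, of progenitors and of the cell cycle were lower in R+. Slc17a6, the vesicular glutamate transporter, differed by -3.46 ± 0.28 and Slc32a1, the vesicular GABA transporter, by -3.33 ± 0.22. Of 16 measured glutamate neuron genes 15 were lower and 0 higher (16 lower adjusted over the list alone; camera adjusted p = 1.18e-23, and 0.0152 with an estimated correlation). Of 14 GABA and glycine neuron genes 11 were lower, including Lhx1 (-2.93 ± 0.23), and 1 was higher, namely Gata3 (12 and 1 adjusted over the list alone; camera adjusted p = 7.51e-14, and 0.00627 with an estimated correlation). The genes furthest below R- also included Otx1 (-4.02 ± 0.67), Pax7 (-3.81 ± 0.40), Nhlh2 (-3.58 ± 0.23), Ebf3 (-3.54 ± 0.15) and the axon guidance receptor Robo3 (-3.44 ± 0.29). For Skor1, Lhx9 and Ebf2 the probe set used gave -3.58, -3.54 and -3.48, and another probe set of each was not past the threshold (-0.93 ± 0.75, -0.90 ± 0.35 and -2.28 ± 0.77).

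Of 45 measured cell cycle genes 40 were lower in R+ and none was higher (42 lower adjusted over the list alone); Mki67, a marker of proliferating cells, differed by -2.67 ± 0.45. The list's camera adjusted p was 6.08e-29, and 0.0885 with an estimated correlation. Neural progenitor and Notch genes were lower in 31 of 41 cases, with 1 higher (35 and 3 adjusted over the list alone; camera adjusted p = 5.93e-25, and 0.00636 with an estimated correlation). With the block 34 were lower and 3 higher. Hes5, a Notch target, differed by -2.49 ± 0.24 and the proneural gene Neurog2 by -3.27 ± 0.24; the exception was Sox1 (1.32 ± 0.17). Red blood cell genes were lower in 5 of 6 cases (all 6 adjusted over the list alone; camera adjusted p = 8.99e-08, and 0.0321 with an estimated correlation), with the embryonic globins Hbb-bh1 at -3.66 ± 0.49 and Hba-x at -2.87 ± 0.24. Of 14 genes of mesenchyme, meninges and pericytes 5 were lower (5 adjusted over the list alone; camera adjusted p = 0.000797, and 0.301 with an estimated correlation). Of 11 macrophage genes 2 were higher, one of them Lyz2 (2.47 ± 0.53), and the list did not pass (2 higher adjusted over the list alone; camera adjusted p = 0.247). Dopamine and noradrenaline neuron genes were lower in 2 of 9 cases, one of them Th (-2.68 ± 0.37), with 2 adjusted over the list alone (camera adjusted p = 0.0293, 0.0522 with the block and 0.318 with an estimated correlation). Motor and cholinergic genes, with 0 higher and 2 lower of 9, and endothelial genes, with 0 and 0 of 12, did not pass as lists (camera adjusted p = 0.0824 and 0.331). Adjusted over the list alone 3 and 0 were lower, and the block gave 3 and 2 lower. Of 16 genes of midbrain, isthmus and anterior hindbrain identity 2 were higher and 9 lower in R+ (2 and 10 adjusted over the list alone; camera adjusted p = 0.00106, and 0.0303 with an estimated correlation). Of 47 adhesion genes 14 were higher and 8 lower (15 and 9 adjusted over the list alone; camera adjusted p = 0.0327, and 0.249 with an estimated correlation).

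In total 1567 of 12845 genes differed between R+ and R-, 557 higher and 1010 lower in R+, and 905 of them at least 2-fold. With the replicate number as a block 2684 genes differed, 1103 higher and 1581 lower, and all 1567 were among them.

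The same comparison in the caudal domain, C+ against C-, also found serotonin genes higher in the YFP-positive cells. Slc6a4 was 9341 ± 1050.2 in C+ and 36 ± 26.5 in C- (log2 difference 7.83 ± 0.32, adjusted p = 6.32e-10). Tph2 differed by 6.0003 ± 0.34, Gchfr by 7.24 ± 0.34 and Ddc, aromatic amino acid decarboxylase, by 5.58 ± 0.14. Of 16 list members 11 were higher and 0 lower (11 and 0 adjusted over the list alone; camera adjusted p = 4.17e-16, and 0.00102 with an estimated correlation). The serotonergic transcription factors were higher in 4 of 7 cases and lower in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.000151, and 0.0359 with an estimated correlation), with Gata3 at 3.96 ± 0.22 and Lmx1b at 2.76 ± 0.28. St18, the lower one, was at -2.43 ± 0.23, but a second probe set gave 0.46 ± 0.75 and the mean of its probe sets did not pass (adjusted p = 0.0741; 5.83e-09 to 0.0741 over 19 alternatives). For Htr1a (2.87 ± 0.24) a second probe set gave 1.37 ± 0.77 (adjusted p = 0.374).

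Ventral progenitor factors, which pattern the floor of the neural tube, were higher in C+ in 5 of 8 cases (5 adjusted over the list alone; camera adjusted p = 1.96e-05, and 0.0134 with an estimated correlation). These were Nkx2-2 (4.14 ± 0.18), Nkx6-1 (2.11 ± 0.37), Foxa1 (2.56 ± 0.28), Foxa2 (2.46 ± 0.33) and the morphogen Shh (2.59 ± 0.35). The neuropeptide precursors Trh (4.66 ± 0.53), Penk (3.98 ± 0.21) and Tac1 (2.72 ± 0.20) were higher in C+ and Sst was lower (-3.44 ± 0.29). Of 26 neuropeptide genes 6 were higher and 8 lower, and the list did not pass (7 and 10 adjusted over the list alone; camera adjusted p = 0.781; median -0.17, mean 0.25 and test direction up). Irs4, an insulin receptor substrate (5.31 ± 0.25), and Arhgef3 (5.31 ± 0.43) were among the most enriched genes. Hox genes were lower in C+ in 11 of 17 cases (12 adjusted over the list alone; camera adjusted p = 6.62e-07, and 0.156 with an estimated correlation), with Hoxa5 at -3.49 ± 0.72 and Hoxb6 at -2.88 ± 0.35. Hoxc5 was at -3.59 ± 0.35, while another of its probe sets gave -0.75 ± 0.51 (adjusted p = 0.486).

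Among the genes furthest below C- were Gbx1 (-4.16 ± 0.50), Fgf15 (-4.01 ± 0.33), Neurod6 (-3.98 ± 0.28), Hbb-bh1 (-3.73 ± 0.49), Robo3 (-3.69 ± 0.29) and Gbx2 (-3.51 ± 0.32). Glutamate neuron genes were lower in 15 of 16 cases and GABA and glycine neuron genes in 11 of 14, with 1 higher (15, 12 and 1 adjusted over the list alone; camera adjusted p = 1.46e-23 and 4.03e-12, and 0.0152 and 0.00636 with an estimated correlation). Cell cycle genes were lower in 34 of 45 cases (39 adjusted over the list alone; camera adjusted p = 2.12e-22, and 0.147 with an estimated correlation), with Mki67 at -2.58 ± 0.45. Progenitor and Notch genes were lower in 27 and higher in 2 of 41 cases, or 29 and 5 with the block (28 and 3 adjusted over the list alone; camera adjusted p = 2.1e-15, and 0.0185 with an estimated correlation). All 6 red blood cell genes were lower (camera adjusted p = 4.09e-08, and 0.0303 with an estimated correlation), with Hba-x at -3.32 ± 0.24. Of 14 mesenchyme genes 7 were lower and 1 was higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.00297, and 0.345 with an estimated correlation); the higher one was Dcn, a matrix proteoglycan (2.50 ± 0.29). Neural crest and early glia genes were lower in 5 of 10 cases and higher in 1, which was Nkx2-2 (5 and 1 adjusted over the list alone; camera adjusted p = 0.00673, and 0.088 with an estimated correlation). Of 51 axon guidance genes 3 were higher and 14 lower, or 9 and 19 with the block (7 and 16 adjusted over the list alone; camera adjusted p = 0.02, and 0.135 with an estimated correlation). Motor and cholinergic genes were higher in 1 and lower in 2 of 9 cases, dopamine and noradrenaline neuron genes in 0 and 2 of 9, and macrophage genes in 0 and 1 of 11, or 1 and 1 with the block. These lists did not pass (camera adjusted p = 0.451, 0.0941 and 0.456; 2, 3 and 1 lower adjusted over the list alone). Endothelial genes were lower in 3 of 12 cases (3 adjusted over the list alone; camera adjusted p = 0.0369, and 0.301 with an estimated correlation).

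In total 1683 genes differed between C+ and C-, 734 higher and 949 lower in C+, or 43.6% higher, and 920 of them at least 2-fold. Scaling each array to one median gave 50.3% higher. The block raised this to 2929, 1344 higher and 1585 lower, with all 1683 among them. Pdlim4 (-3.62 ± 0.48), Skor1 (-3.68 ± 0.20, second probe set -1.73 ± 0.75), Slc17a6 (-3.59 ± 0.28) and Hoxc5, given above, completed the genes furthest below C-.

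**Figure D2:**
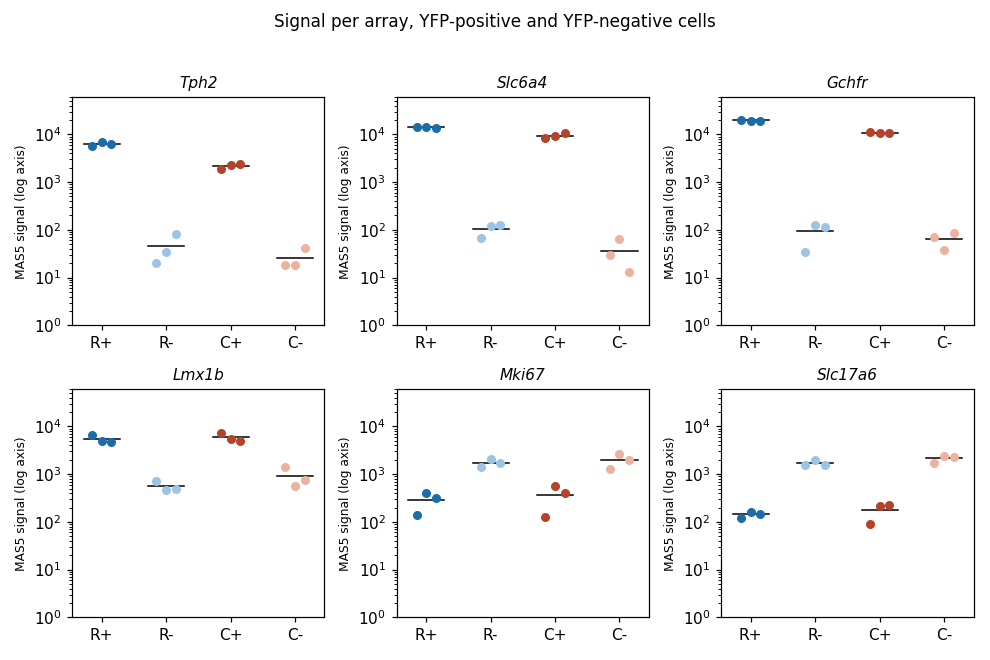
MAS5 signal per array (vertical axis, log scale) of 6 genes in R+, R-, C+ and C-, with a point per array and a bar at each group mean. Tph2, Slc6a4, Gchfr and Lmx1b lay higher in all YFP-positive arrays than in the YFP-negative arrays of their domain, and Mki67 and Slc17a6 lay lower.

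Genes higher in both YFP-positive populations were candidates for a shared serotonergic programme. There were 347 of them, against 31.8 if the 557 and 734 genes were independent, and 657 with the block, against 115.4. Many cell cycle and progenitor genes were lower in both populations, so some of the 347 may mark postmitotic neurons in general. No comparison with other postmitotic neurons was made. The comparisons share no array, but both used the same spread per gene, estimated over all 12 arrays. A gene with a small spread is more easily called in both. The counts for independent lists may therefore understate the overlap to be expected. The 10 genes with the largest smaller difference were Gchfr, Slc6a4, Tph2, Cryba2, 1700042O10Rik, Scg2, Gch1, Slc18a2, Maob and AW551984, the last with 4.04 ± 0.13 in the rostral and 4.36 ± 0.13 in the caudal domain. Maob, a monoamine oxidase, differed by 4.21 ± 0.38 and 5.08 ± 0.38, and Maoa by 2.91 ± 0.19 and 2.93 ± 0.19. Penk differed by 3.04 ± 0.21 rostrally and Chgb by 3.22 ± 0.16 and 3.30 ± 0.16. Of the general neuronal genes 6 were higher and 4 lower among 37 rostrally (6 and 4 adjusted over the list alone; camera adjusted p = 0.00473, and 0.353 with an estimated correlation), and 6 and 3 caudally (7 and 3 adjusted over the list alone; camera adjusted p = 0.0941). With the block 16 were higher and 4 lower rostrally, and 13 and 4 caudally. The neurofilament gene Nefl was lower in both (-1.33 ± 0.15 and -1.23 ± 0.15). A further 614 genes were lower in both, against 74.6 for independent lists, and 942 with the block, against 195.1.

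The comparison of R+ with C+ asked which genes distinguish rostral from caudal serotonergic cells. Hox genes, which pattern the hindbrain along its length, were lower in R+ in 13 of 17 cases (13 adjusted over the list alone; camera adjusted p = 2.95e-19, and 0.0185 with an estimated correlation). Hoxb5 was 19.3 ± 26.6 in R+ and 2869.7 ± 754 in C+ (-6.95 ± 0.50), and Hoxb3 differed by -5.93 ± 0.35. Hoxc4 (-5.73), Hoxd3 (-5.54), Hoxa5 (-5.08), Hoxb4 (-4.87) and Hoxa3 (-4.64) followed, as did Hoxc5 (-4.67), of which one other probe set gave -0.47 ± 0.74 (adjusted p = 0.791). In the other direction, genes of midbrain, isthmus and anterior hindbrain identity were higher in R+ in 5 and lower in 2 of 16 cases (7 and 3 adjusted over the list alone; camera adjusted p = 0.0107, and 0.0788 with an estimated correlation). En1 was 1457 ± 122 in R+ and 103 ± 47.6 in C+ (3.79 ± 0.29), En2 differed by 4.04 ± 0.34 and Cnpy1 by 3.10 ± 0.26. One of the lower members was Meis2, a homeobox cofactor (-2.31 ± 0.17). The rostral and caudal arrays being compared also differed in their beta-actin ratio, 3.24 ± 0.52 against 5.79 ± 1.20.

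Some serotonin genes were higher in R+ than in C+. Of 16 members 3 were higher in R+ and none lower (5 and 1 adjusted over the list alone; camera adjusted p = 5.88e-05, and 0.0138 with an estimated correlation). With the block 5 were higher and 1 lower. Tph2 differed by 1.502 ± 0.34 (adjusted p = 0.0155), Slc18a2 by 1.59 ± 0.18 and Ddc by 1.22 ± 0.14. The Tph2 call was lost when R+ replicate 2 (adjusted p = 0.0536), C+ replicate 2 (0.0568) or R+ replicate 3 (0.0659) was left out. With the beta-actin ratio and the block together Tph2 and Slc18a2 did not pass (adjusted p = 0.292 and 0.132). Over 19 alternatives the adjusted p ranged from 0.000199 to 0.292 for Tph2 and from 1.74e-05 to 0.132 for Slc18a2. Serotonergic transcription factors were higher in 3 of 7 cases (3 with 1 lower adjusted over the list alone; camera adjusted p = 0.0462, 0.107 with the block and 0.249 with an estimated correlation); their median was -0.12 and their mean 1.08, so that median and test differ in sign. The block gave 3 higher and 1 lower. The higher ones were En1 and En2, which also stand in the midbrain, isthmus and anterior hindbrain list, and St18 (0.88 ± 0.23), which was lower in the YFP-positive cells of both domains. A second St18 probe set gave -0.58 ± 0.75. The St18 call was lost under 8 of 19 alternatives (adjusted p = 0.000472 to 0.852), among them without R+ replicate 2 (0.112) or 3 (0.105) and without C+ replicate 1 (0.0656) or 2 (0.0777). Gata2 (-0.38 ± 0.15), Gata3 (-0.25 ± 0.22), Lmx1b (-0.12 ± 0.28) and Insm1 (-0.42 ± 0.21) were not called.

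Among genes also enriched over the YFP-negative cells of their domain, R+ was higher than C+ for the homeobox genes Hmx2 (4.80 ± 0.38) and Hmx3 (2.67 ± 0.39), and for Pdzrn4 (3.92 ± 0.31), Vstm2a (3.07 ± 0.20), the heparan sulfate enzyme Hs6st2 (2.76 ± 0.25) and A930009L07Rik (2.67 ± 0.16). Cited1 (4.27), the cadherin Cdh8 (3.96) and Otor (2.91) were also higher, but lost the call with the block and the beta-actin ratio together (adjusted p = 0.366, 0.117 and 0.47), and Cited1 also with the ratio alone (0.135). C+ was higher for the homeobox gene Shox2 (-5.25 ± 0.17), the tachykinin precursor Tac1 (-4.70 ± 0.20), Nkx6-1 (-4.39 ± 0.37), Dcn (-4.28 ± 0.29), Trh, the precursor of thyrotropin-releasing hormone (-4.17 ± 0.53), Ndnf (-3.63 ± 0.22) and Irs4 (-3.33 ± 0.25). Calb2, a calcium-binding protein (-4.32), Trmt9b (-2.98) and Nell1 (-2.91) were also higher in C+. Their calls did not hold with the block and the beta-actin ratio together (adjusted p = 0.0606, 0.0968 and 0.508), nor did that of Hoxa5 (0.136). With the ratio alone the calls of Trmt9b (0.0842), Nell1 (0.0964) and Hoxa5 (0.0732) were lost as well. For all of these genes the lowest adjusted p over the alternatives was under 0.001.

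**Figure D3:**
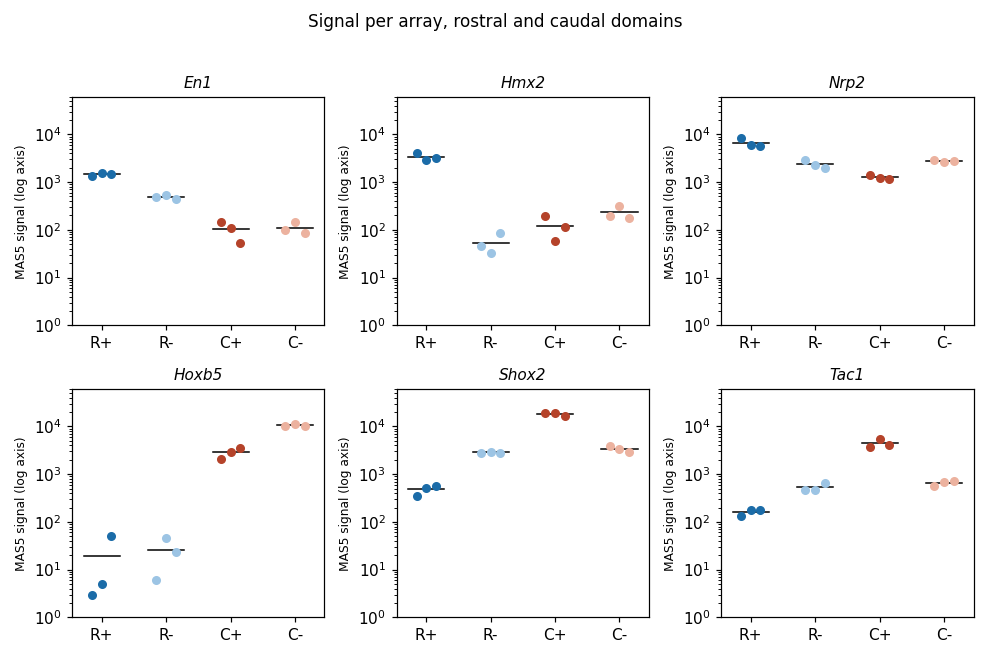
MAS5 signal per array (vertical axis, log scale) of 6 genes in R+, R-, C+ and C-, with a point per array and a bar at each group mean. En1, Hmx2 and Nrp2 lay higher in R+ than in C+, and Hoxb5, Shox2 and Tac1 lay higher in C+ than in R+, on all arrays.

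Genes of axon guidance, adhesion and migration differed in both directions, and none of these lists passed the camera test. Of 51 axon guidance genes 6 were higher and 6 lower in R+ (7 and 10 adjusted over the list alone; camera adjusted p = 0.781; median -0.03, mean -0.01 and test direction up). Nrp2, a semaphorin receptor, was 6716 ± 1364 in R+ and 1267 ± 131 in C+ (2.38 ± 0.17), and the ephrin receptor Epha3 differed by -1.89 ± 0.16. Of 47 adhesion genes 8 were higher and 9 lower (10 and 11 adjusted over the list alone; camera adjusted p = 0.544), with Cdh13 at 2.25 ± 0.15 and Cntnap5a at -2.85 ± 0.17. Of 24 migration and trophic genes 1 was higher and 6 lower (2 and 7 adjusted over the list alone; camera adjusted p = 0.256), namely the GDNF receptor Gfra1 (2.51 ± 0.14) on the higher side and Reln (-2.20 ± 0.18) among the lower. Of 26 neuropeptide genes 2 were higher and 5 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.419). Npy was at -2.08 ± 0.16 and Penk at -1.24 ± 0.21, of which Penk lost its call with the block and the beta-actin ratio together (adjusted p = 0.0707). Of 40 transmitter receptor genes 3 were higher and 6 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.277), with the kainate receptor subunit Grik3 at -2.54 ± 0.25. With the block 9 axon guidance, 11 adhesion, 3 migration and 5 receptor genes were higher and 11, 14, 7 and 7 lower. Gad1, the GABA-synthesizing enzyme, was at -3.47 ± 0.19 with the brighter probe set and at -0.74 ± 0.52 with a second, dim one (adjusted p = 0.486). Of the mesenchyme, macrophage and cell cycle genes 0, 1 and 3 were higher and 1, 0 and 0 lower (0, 2 and 3 higher and 4, 0 and 0 lower adjusted over the list alone). With the block 2 macrophage genes were higher and 5 mesenchyme genes lower. These lists passed with the preset correlation (camera adjusted p = 0.0157, 0.0326 and 0.0304) and not with an estimated one (0.406, 0.388 and 0.685), the macrophage list not with the block either (0.0628). All these R+ and C+ values carry the difference in beta-actin ratio given above.

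In total 940 genes differed between R+ and C+, 364 higher and 576 lower in R+, or 38.7% higher; scaling each array to one median gave 48.5% higher. Of these 355 differed at least 2-fold. The block raised the count to 2795, and using only the 6 arrays compared gave 605. Leaving out a single array gave 503 (R+ replicate 1), 391 (R+ replicate 3), 1744 (C+ replicate 1), 385 (C+ replicate 2) and 402 (C+ replicate 3), and the beta-actin ratio as a covariate gave 216.

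The YFP-negative cells of the domains, R- against C-, gave the regional background for the previous comparison. Hox genes were lower in R- in 12 of 17 cases (15 adjusted over the list alone; camera adjusted p = 2.19e-36, and 0.00627 with an estimated correlation). Hoxb5 was at -8.41 ± 0.50, Hoxa5 at -7.49 ± 0.72, Hoxc4 at -7.48 ± 0.56, Hoxa4 at -5.92 ± 0.43 and Hoxb6 at -5.53 ± 0.35. Hoxc5 was at -7.15 ± 0.35, but one of its other probe sets gave -1.05 ± 0.51 (adjusted p = 0.448). Midbrain, isthmus and anterior hindbrain genes were higher in 9 and lower in 2 of 16 cases (11 and 3 adjusted over the list alone; camera adjusted p = 5.19e-08, and 0.00627 with an estimated correlation), and 9 and 4 with the block, with En2 at 5.70 ± 0.34, Otx2 at 4.85 ± 0.53 and Otx1 at 4.66 ± 0.67. Tal2 was at 4.92 ± 0.49, and its other probe set gave 1.54 ± 0.41 (adjusted p = 0.0952). Gbx2, a hindbrain gene of that list, was lower (-3.50 ± 0.32). The beta-actin ratio differed here too, 3.52 ± 0.78 against 5.75 ± 1.69.

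Ventral progenitor factors were higher in R- in 4 of 8 cases (4 adjusted over the list alone; camera adjusted p = 2.04e-07, and 0.00636 with an estimated correlation), with Foxa2 at 3.84 ± 0.33, Foxa1 at 2.94 ± 0.28, Nkx2-2 at 1.63 ± 0.18 and Shh at 1.90 ± 0.35. Ddc was 1458 ± 243 in R- and 126 ± 9.02 in C- (3.43 ± 0.14), and a second Ddc probe set gave 2.35 ± 0.38 (adjusted p = 0.00526). Serotonin genes were higher in 4 of 16 cases (6 adjusted over the list alone; camera adjusted p = 1.1e-06, and 0.00636 with an estimated correlation), and serotonergic transcription factors in 4 of 7 (5 with 1 lower adjusted over the list alone; camera adjusted p = 2.03e-07, and 0.0132 with an estimated correlation), namely En1 (2.10 ± 0.29) and En2, both also members of the midbrain list, Gata2 (0.80 ± 0.15) and Gata3 (0.90 ± 0.22). With the block 5 of these factors were higher and 1 lower. Over 19 alternatives Gata3 lost its call under 9 (adjusted p = 0.000675 to 0.262), 5 of them leaving out an array, namely R- replicate 1 (0.104), 2 (0.0839) or 3 (0.11) and C- replicate 2 (0.156) or 3 (0.138). Gata2 lost it under 3 (0.000311 to 0.102), one of them without C- replicate 3 (0.0533), and its second probe set gave 0.63 ± 0.24 (adjusted p = 0.296). With the block and the beta-actin ratio together the calls of Shh, En1 and Otx1 were lost (adjusted p = 0.0753, 0.102 and 0.104). Slc18a2 differed by 0.89 ± 0.18, but its call was lost without R- replicate 3 (adjusted p = 0.0844), without C- replicate 3 (0.0697) and with the beta-actin ratio as a covariate (0.16); over 19 alternatives its adjusted p ranged from 0.00401 to 0.521. Of 9 dopamine and noradrenaline neuron genes 1 was higher (2 adjusted over the list alone and 2 with the block; camera adjusted p = 0.0941), namely Nr4a2, a factor of dopamine neurons (1.61 ± 0.18). Of its 3 other probe sets one passed (1.18 ± 0.23, adjusted p = 0.0186) and the others did not (1.54 ± 0.45 and 0.74 ± 0.61), nor did the mean of all its probe sets (adjusted p = 0.0531; 9.95e-06 to 0.0531 over 19 alternatives). Slc6a5, the glycine transporter, was lower (-3.20 ± 0.33), as was Npy (-2.74 ± 0.16), and the GABA neuron factor Tal1 was higher (1.63 ± 0.19). Cell cycle genes were higher in 2 of 45 cases (3 adjusted over the list alone; camera adjusted p = 8.99e-08, and 0.401 with an estimated correlation), with Ccnd2 at 1.73 ± 0.30; the block gave 11 higher and 0 lower. Of the progenitor, mesenchyme and general neuronal genes 3, 0 and 0 were higher and 0, 2 and 4 lower (5, 0 and 0 higher and 0, 5 and 6 lower adjusted over the list alone). With the block 10, 0 and 2 were higher and 1, 5 and 10 lower. These lists passed with the preset correlation (0.00023, 0.000151 and 0.0305) and not with an estimated one (adjusted p = 0.249, 0.249 and 0.441); their median differences were 0.23, -0.66 and -0.19. Motor and cholinergic genes, with 0 of 9 higher and 0 lower, did not pass (0 and 2 adjusted over the list alone; camera adjusted p = 0.206), nor did immediate early and dissociation stress genes, with 1 of 25 higher (1 adjusted over the list alone; 0.917). With the block 2 motor genes were lower, and 2 early and stress genes were higher and 1 lower. In R+ against R- and in C+ against C- the early and stress list had 1 higher and 6 lower members each. Adjusted over the list alone these were 1 and 7, and 2 and 7. The block gave 2 and 8 in C+ against C-. The list did not pass in either (camera adjusted p = 0.146 and 0.124).

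In total 363 genes differed between R- and C-, 135 higher and 228 lower in R-, or 37.2% higher; scaling each array to one median gave 46.2% higher. Of these 186 differed at least 2-fold, and the block gave 1310. Without C- replicate 2 the count was 238, without R- replicate 3 it was 198 and without C- replicate 3 it was 220, and the beta-actin ratio as a covariate gave 216. Further genes higher in R- were Dmrta2 (4.08 ± 0.35), Six3 (3.15 ± 0.28) and Cnpy1 (3.09 ± 0.26). Of the genes higher in R+ than in C+, 47 were also higher in R- than in C-, against 3.83 for independent lists, and 128 were lower in both, against 10.2. With the block these were 302, against 54.1, and 415, against 90.8. Here too both comparisons used the same spread per gene, so the counts for independent lists may be too low.

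A direct test asked whether the rostral-caudal difference of YFP-positive cells differed from that of YFP-negative cells. Shox2 was 478 ± 120.4 in R+, 2860 ± 67.1 in R-, 18206 ± 1238 in C+ and 3353 ± 447 in C-, so that the difference of differences was -5.03 ± 0.24 (adjusted p = 3.81e-08). Tac1 (-4.39 ± 0.28), Irs4 (-5.33 ± 0.35) and Mlf1 (-2.96 ± 0.22) went the same way. Diras2 (-3.16 ± 0.21) did too, but another probe set gave -0.29 ± 0.80 and the mean of its probe sets did not pass (adjusted p = 0.0598; 2.77e-08 to 0.0598 over 24 alternatives). In the other direction lay A930009L07Rik (2.86 ± 0.22), Hmx2 (6.76 ± 0.53), Nrp2 (2.62 ± 0.23), Gfra1 (2.19 ± 0.20) and Pdzrn4 (4.35 ± 0.43). Another probe set each of Shox2, Nrp2 and Gfra1 gave -5.56 ± 1.21, 2.38 ± 0.56 and 1.95 ± 0.52 and was not past the threshold, while one more of Nrp2 was (2.94 ± 0.36). Ventral progenitor factors stood apart as a list, with 5 of 8 members called (5 adjusted over the list alone; camera adjusted p = 1.41e-10, and 0.00442 with an estimated correlation). These were Foxa2 (-4.03 ± 0.47), Nkx6-1 (-3.85 ± 0.52), Shh (-2.75 ± 0.49), Foxa1 (-2.35 ± 0.39) and Nkx2-2 (-1.37 ± 0.25). Without the trend in eBayes Shh did not pass (adjusted p = 0.0563, and 5.94e-05 to 0.0563 over 24 alternatives). Between R+ and C+ only Nkx6-1 was called, or 2 lower members with the block, and the list did not pass (camera adjusted p = 0.752). Without the block Foxa2 (-0.19), Shh (-0.85), Foxa1 (0.60) and Nkx2-2 (0.26) were not called there. In the YFP-negative cells they were higher in R- than in C- (3.84, 1.90, 2.94 and 1.63). Their difference of differences thus came mainly from the YFP-negative cells. Ddc (-2.21 ± 0.20) also differed, but its second probe set gave -0.43 ± 0.54 and the mean of its probe sets did not pass (adjusted p = 0.0895; 3.36e-06 to 0.0895 over 24 alternatives). Grik3 (-1.62 ± 0.35) lost its call under 11 of 24 alternatives, 8 of them leaving out an array. Of 47 adhesion genes 4 were called with a positive and 4 with a negative value, or 8 and 7 with the block, and the list did not pass (9 and 6 adjusted over the list alone; camera adjusted p = 0.49). Among them were Cntnap5a (-3.06 ± 0.24) and Cdh13 (2.09 ± 0.22), and a second Cdh13 probe set gave 1.98 ± 0.48 (adjusted p = 0.131). In total 150 genes passed, 63 with a positive and 87 with a negative difference of differences, and 340 with the block. General neuronal genes did not pass as a list (camera adjusted p = 0.136) but did with the block (0.0356).

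**Figure D4:**
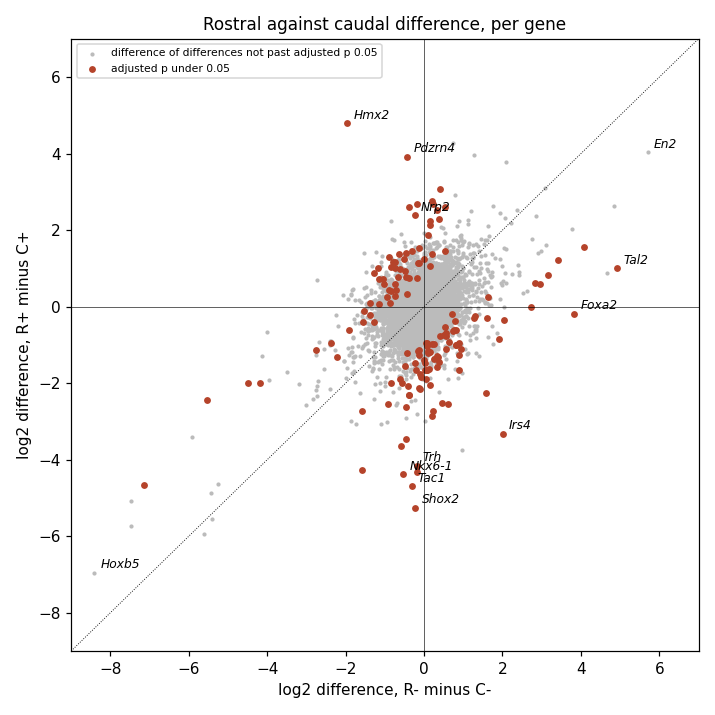
Log2 difference R+ minus C+ (vertical axis) against log2 difference R- minus C- (horizontal axis) for 12845 genes, with the dotted line marking equal differences. The 150 genes whose difference depends on YFP (red points) lie off that line, while En2 and Hoxb5 differ in the same direction in both kinds of cell.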

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

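Chosen only after the results were seen were the tests of the beta-actin covariate, also on the difference of differences, the replicate 1 arrays, serotonergic and dopaminergic cells in R-, GABA neurons in C+, the regroupings of the gene list tests with an estimated correlation, and the splits of differences within a replicate number.

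The rostral-caudal difference depended on YFP for 150 genes. Over 100 draws of the 12 arrays into 4 groups, the real one included, 1 gave as many, the highest other being 17. These draws do not decide whether chance gave the count: they mix populations that differ, and the median residual SD was 0.321 to 0.393 in the other draws against 0.281. Of the 99 others, 4 parted all same-numbered arrays and gave at most 3. The differences of YFP-positive minus YFP-negative arrays within a replicate number allow 10 splits into 3 and 3, too few for a share under 0.05. Of these 1 gave as many as the real 409 genes, and the highest other was 0. Lists whose shift differed between YFP-positive and YFP-negative cells had medians of -1.86 (ventral progenitor factors), 1.43 (Hox genes), -0.54 (midbrain, isthmus and anterior hindbrain identity), -0.25 (cell cycle), -0.17 (neural progenitor and Notch genes) and 0.64 (macrophages and microglia). With an estimated correlation their adjusted p was 0.00442, 0.15, 0.0825, 0.685, 0.301 and 0.317, so that only the first passed. Members called with a positive and a negative difference of differences numbered 2 and 0 of 17 Hox genes, 0 and 3 of 16 midbrain, isthmus and anterior hindbrain genes, 0 and 0 of 45 cell cycle genes, 0 and 2 of 41 progenitor genes and 0 and 0 of 11 macrophage genes. Adjusted over the list alone these numbers were 5 and 0, 3 and 6, 0 and 0, 0 and 5 and 1 and 0. With the block the counts were 4 and 0, 3 and 4, 0 and 0, 0 and 7 and 1 and 0. With the preset correlation their camera adjusted p was 3.89e-07, 0.0136, 0.0287, 0.00134 and 0.00915.

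Single genes whose difference depended on YFP, on the positive side, were A930009L07Rik 2.86, Cdh13 2.09, Gfra1 2.19, Hmx2 6.76, Hmx3 2.45, Hoxb6 3.09, Hoxc5 2.47, Hs6st2 2.54, Nrp2 2.62, Pdzrn4 4.35 and Vstm2a 2.67 on the log2 scale. On the negative side were Calb2 -4.14, Cntnap5a -3.06, Dcn -2.69, Ddc -2.21, Diras2 -3.16, Dmrta2 -2.53, Epha3 -1.28, Foxa1 -2.35, Foxa2 -4.03, Gad1 -2.997, Gata2 -1.18, Grik3 -1.62, Irs4 -5.33, Meis2 -1.93, Mlf1 -2.96, Ndnf -3.04, Nkx2-2 -1.37, Nkx6-1 -3.85, Nr4a2 -1.91, Shh -2.75, Shox2 -5.03, Six3 -2.32, Tac1 -4.39, Tal2 -3.92 and Trh -3.98. Leaving out 1 array ended some of these calls. Trh did not pass without C+ replicate 1, 2 or 3 (adjusted p = 0.0771, 0.0671 and 0.0811), and Dmrta2 not without R- replicate 1 (0.0552) or C+ replicate 2 (0.0608). Hoxc5 did not pass without R+ replicate 2 (0.0598) or 3 (0.0618), C+ replicate 2 (0.0739), or C- replicate 1 (0.0633), 2 (0.0764) or 3 (0.0838). Hmx3 did not pass without R+ replicate 1 (0.161), 2 (0.0636) or 3 (0.121), R- replicate 1 (0.0812), 2 (0.129) or 3 (0.088), C+ replicate 1 (0.0672) or 2 (0.0953), or C- replicate 1 (0.0988) or 3 (0.13). Grik3 did not pass without R+ replicate 1 (0.0951) or 3 (0.0954), R- replicate 2 (0.116) or 3 (0.088), C+ replicate 2 (0.129) or 3 (0.0653), or C- replicate 1 (0.0988) or 3 (0.102). Over all 24 alternatives the adjusted p reached from 0.00118 to 0.0811 for Trh, 0.00423 to 0.0664 for Dmrta2, 0.000568 to 0.383 for Hoxc5, 0.00756 to 0.203 for Hmx3 and 1.87e-05 to 0.129 for Grik3. With the mean of a gene's probe sets Gata2, Nr4a2, Hoxc5, Ddc, Diras2 and Grik3 did not pass (0.059, 0.457, 0.125, 0.0895, 0.0598 and 0.0509). Another probe set did not pass for Gad1 (-0.31), Gata2 (-0.68), Tal2 (-1.63), Epha3 (-1.29), Meis2 (-2.24) and Nr4a2 (-0.97 and -0.15), and one of Hoxc5 had the opposite sign (-1.07); other probe sets of Meis2 and Nr4a2 passed.

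More genes differed between R+ and C+ (940) than between R- and C- (363), but the size of this excess moved with single arrays. The ratio of the counts was 1.45, 2.07 and 1.21 without R+ replicate 1, 2 or 3. It was 3.97, 1.28 and 1.18 without C+ replicate 1, 2 or 3, and 3.03 to 4.37 without an R- or C- array. Leaving out an array leaves fewer arrays to the comparison that uses it. That alone did not set the counts, since without C+ replicate 1 the R+ against C+ count rose to 1744. The number of arrays and the values of the array left out are mixed here. These ratios therefore cannot decide whether the excess rests on single arrays. With the block the counts were 2795 and 1310. The ratio of the R+ against C+ count to the R- against C- count was 5.01 with replicates 2 and 3 alone and 2.59 with all arrays. The excess was thus present without the replicate 1 arrays. Each replicate number holds an array of every population, so a batch that shifts them alike could not shift either comparison. It could change the counts only through the spread, which this ratio does not isolate. The ratio therefore does not decide what part a batch of replicate 1 had. RNA quality stays open for this excess: with the beta-actin ratio as a covariate both counts became 216, and 126 and 113 with the block added, but the median absolute difference of the 940 genes went only from 0.84 to 0.68 while its SE rose from 0.183 to 0.247, all 940 keeping their sign, so that part of the loss may be precision, and within groups 72.1% of the 940 had the sign of their slope on the ratio, inside the 26.7 to 73.3% of random directions. For 132 of the 940 the difference of differences passed with the ratio as a covariate, all 132 also with the block added. A beta-actin trend shared equally by YFP-positive and YFP-negative cells would by itself give no difference of differences. It could still be the whole difference between R+ and C+ where the difference of differences comes from the YFP-negative cells. Ddc, for example, differed by 1.22 between R+ and C+ and by 3.43 between R- and C-. The test thus does not decide the cause for these 132. A difference between the domains' serotonergic cells stays open for them as a hypothesis. So do such a trend and RNA quality that differs between C+ and C- (Gapdh ratio 3.20 ± 1.52 and 2.03 ± 0.48). For the other 808 as a whole domain and RNA quality cannot be told apart either, because the beta-actin ratio follows the domain. The Hox list passed between R+ and C+ under all 25 alternatives with the preset correlation, that ratio as a covariate included (camera adjusted p at most 7.33e-15). This argues against the beta-actin ratio as the whole cause for that list.

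Ddc was higher in R- than in C- by 3.43 ± 0.14. Serotonergic cells with the profile of R+ left in R- are argued against, because Gchfr, Slc6a4, Slc18a2 and Tph2 stood in R- at 0.474 to 2.19% of their R+ signal and Ddc at 9.69%. These 4 were the other serotonin genes with the highest R+ signal, chosen after a first form of the test. That first form, over all 10 other called serotonin genes, had a median of 4.07% and a range up to 54.3% (Pcbd1). It did not decide, since several of them are expressed by other cells. Serotonergic cells in R- with low levels of the 4 genes were not tested. Dopaminergic neurons, which also express Ddc, may contribute: of 5 measured markers 2 were higher in R- (Nr4a2 and Slc18a2), too few to decide. Nr4a2 did not pass with the mean of its probe sets (adjusted p = 0.0531). Slc18a2 is also a serotonin list gene, and its call was lost without R- replicate 3 (adjusted p = 0.0844) or C- replicate 3 (0.0697). Th was not called between R- and C-. A regional difference of other cells stays open, untested.

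Gad1 in C+ stood at 89.6% of its C- signal and above R+. GABA neurons of the YFP-negative kind in C+ are argued against, since 12 other GABA and glycine genes stood in C+ at a median of 15.5% of their C- signal (upper quartile 20.5%, highest 37.6% for Dlx2). A Gad1 probe set that measures another transcript is a candidate explanation: the second probe set gave -0.74 ± 0.52, where the first gave -3.47 ± 0.19. That second probe set was dim, with mean signals of 33.7, 122, 69.3 and 166 in R+, R-, C+ and C-, which limits this reading. Expression of Gad1 by caudal serotonergic cells stays open and was not tested apart from these probe sets.

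With 10 splits of 6 arrays into 3 and 3 the splits are too few for a share under 0.05. The real values, with only the arrays compared in the fit, were 1535 for R+ against R-, 1334 for C+ against C-, 605 for R+ against C+ and 305 for R- against C-, the highest other being 0 in each case, and 1 of 10 splits gave as many in each; the 4 splits of each that parted all pairs had a highest other of 0. For genes higher in both YFP-positive populations 1 of 100 draws gave as many as 347, the highest other being 0, and with an estimated correlation 1 of 100 gave as many as the 21 list tests, the highest other being 2. These draws mix populations too and do not decide. For the gene list tests 14 of 100 draws gave as many as the 47 that passed, up to 64. Mixed draws still carry differences between the populations, so this share is no measure of chance either. Chance was not excluded for this count.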

How the results depend on the processing

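The settings of replicates 2 and 3 alone, the beta-actin covariate and the block with that covariate were tests chosen only after the results were seen. Of the 105 results of genes picked by size and p, 96 kept their call under every alternative run for single genes, which leaves out each probe set by itself and the 2-fold minimum. Another 9 lost it under some (8 only with the covariate) and 0 turned direction. Picking by large differences or small p favours kept calls, so that these 105 are no measure of the stability of other genes. Of all 693 called results of list members, whether quoted or not, 428 kept it, 264 lost it under some alternative (44 only with the covariate, 180 when an array was left out) and 2 changed sign; the quoted members were chosen with this known and are no measure of stability. The replicate block gave 2684 genes for R+ against R-, 2929 for C+ against C-, 2795 for R+ against C+, 1310 for R- against C-, 340 for the difference of differences and 657 higher in both; it removed none of the calls in the 5 contrasts, and it changed 4 list tests, whose blocked values stand beside them, and no other list test. A minimum of 2-fold gave 905, 920, 355 and 186 for the first 4, because it drops small differences. For R+ against C+, eBayes without trend gave 609, only the arrays compared 605 and replicates 2 and 3 alone 1813. The beta-actin covariate gave 216 for R+ against C+ and 216 for R- against C-. The block with that covariate gave 2551, 2885, 126, 113, 305 and 652 higher in both. Estimated correlation left 21 of the 47 list tests. With the preset correlation 31 of the 47 kept their call under every other alternative run for lists and 16 lost it under some, 13 of them when an array was left out; 0 turned direction. By number of alternatives that ended the call, with the range of the adjusted p over all of them, those lost between R+ and C+ were serotonergic transcription factors (16; 0.000509 to 0.181), macrophages (7; 0.0172 to 0.979), cell cycle (6; 8.4e-13 to 0.739), mesenchyme (4; 0.00123 to 0.213) and midbrain identity (2; 0.00115 to 0.102). Between R+ and R- they were dopamine neurons (5; 0.000765 to 0.114), adhesion (4; 0.0153 to 0.0896) and general neuronal genes (1; 8.48e-05 to 0.0625). Between C+ and C- they were endothelial cells (3; 0.0109 to 0.132), axon guidance (2; 0.00799 to 0.112), mesenchyme (1; 0.000733 to 0.0857) and neural crest (1; 0.00139 to 0.168). Between R- and C- this was general neuronal genes (6; 2.8e-09 to 0.638), and in the difference of differences cell cycle (7; 7.23e-05 to 0.577), midbrain identity (3; 0.000875 to 0.0802) and macrophages (2; 0.000688 to 0.0518). Except for the 2-fold minimum, the cause was not tested. Leaving out 1 array gave 1048 to 1422 for R+ against R-, 1193 to 1872 for C+ against C-, 385 to 1744 for R+ against C+, 198 to 342 for R- against C-, 103 to 182 for the difference of differences, 252 to 358 higher in both and 40 to 51 list tests. Signal near background limits folds of dim genes, and no detection call was used.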

Other observations

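The genes of both paragraphs here were chosen after their values were seen. A pair of receptor genes stood among those higher in both YFP-positive populations. Calcr, the calcitonin receptor, was 1312 ± 218 in R+ and 103 ± 23 in R- (3.56 ± 0.29) and 2101 ± 400.0 in C+ and 140 ± 79 in C- (3.92 ± 0.29; adjusted p = 9.6e-07 and 3.14e-07). Ptger3, a prostaglandin E receptor, differed by 2.30 ± 0.39 and 3.69 ± 0.39. The adhesion gene Negr1 was higher in both domains as well, by 1.42 ± 0.14 and 1.72 ± 0.14. The difference between the domains was not past the threshold for Calcr, Ptger3 or Negr1 (adjusted p of the difference of differences 0.963, 0.506 and 0.891).

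Some genes crossed: 9 were higher in R+ than R- and lower in C+ than C-, and 11 the reverse, against 41.2 and 57.7 for independent lists; with the block these were 22 and 26, against 136.1 and 165.4. Nrp2 was 1.51 ± 0.17 rostrally and -1.11 ± 0.17 caudally, Gfra1 0.78 ± 0.14 and -1.41 ± 0.14, Pdzrn4 2.97 ± 0.31 and -1.38 ± 0.31, and A930009L07Rik 1.16 ± 0.16 and -1.70 ± 0.16. The reverse held for Shox2 (-2.59 ± 0.17 and 2.44 ± 0.17), Tac1 (-1.67 ± 0.20 and 2.72 ± 0.20), Nkx6-1 (-1.74 ± 0.37 and 2.11 ± 0.37), Foxa2 (-1.57 ± 0.33 and 2.46 ± 0.33) and Ndnf (-1.58 ± 0.22 and 1.47 ± 0.22). Foxa2 was not called between R+ and C+ themselves (-0.19, limma adjusted p = 0.783). Another probe set each of Nrp2, Gfra1 and Shox2 had the same sign and did not pass in the caudal domain (-0.76 ± 0.40, -0.97 ± 0.37 and 2.62 ± 0.85), while one more of Nrp2 passed (-0.96 ± 0.25). In the rostral domain those of Gfra1 and Shox2 did not pass either (0.98 ± 0.37 and -2.95 ± 0.85).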
